A study of Drosophila melanogaster with 3 samples.

How the data were processed

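Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster larvae of mixed sex, at the wandering stage of the last larval instar. The larvae carried h, the gene for the HES-family repressor Hairy, fused to GFP at its C terminus, and chromatin sheared by sonication was precipitated with an antibody against GFP, per the labels. The samples were 3 biological replicates of 1 group, so no comparison between conditions was possible. The current annotation names the gene hry, and that symbol is used throughout. Data of the control library named in the labels were not analysed here. Peaks that do not depend on the fusion therefore cannot be told from its binding.

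The authors deposited peak lists, made separately on builds dm6 and dm3. Each replicate has a list of 30000 peaks intended as input for the irreproducible discovery rate (IDR) procedure, which keeps peaks whose ranks are repeated between replicates. A list of 30000 pooled peaks and a shorter IDR-thresholded list, called the reproducible list here, cover all replicates together, per the labels and the notes deposited with the lists. Replicate peaks were therefore called per sample, and the reproducible list rests on the same replicates, so its recovery in them is not independent evidence. The signal value of a peak is a score without a stated scale, given by the authors, and was used only to rank peaks within a list. The authors also gave each peak a −log10 q-value, and 8170 of the 10233 reproducible peaks share its highest value of 4.21, so it was not used for ranking. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Within each build, every reproducible peak was among the strongest of the pooled list by signal value, with 10233 of 10233 identical entries on dm6.

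Read depth is unknown, since peak lists hold no read totals, and no interval that needs depth is given. Exact binomial intervals and tests over peaks or genes cover counting error only, because neighbouring peaks and genes are not independent replicates. The spread between the 3 replicates is therefore given beside them as a mean and SD. To compare lists of equal length, the 10233 strongest peaks of each replicate were taken, called its top list.

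Coordinates are 1-based positions on dm6, and dm3 positions were not converted. Genes came from Ensembl annotation release 115 for the matching assembly, with 13945 protein-coding genes and 19607 distinct gene-specific transcription start sites (TSSs) on arms 2L, 2R, 3L, 3R, 4 and X. A summit was at a promoter if it lay within 500 bp of a protein-coding TSS, and distal otherwise. Recovery was the percentage of reproducible summits inside a peak of a replicate's top list, set beside 100 random placements on the same arms. Promoter shares were compared with 10 random positions per peak by a two-sided Fisher's exact test. Of the reproducible summits, 6 lie 1 position past the end of their own peak and were kept.

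The 9 motifs fixed in advance were searched on both strands within 100 bp of each summit and in a window of the same size centred 1000 bp away on a random side, with an exact McNemar test and Benjamini-Hochberg adjustment over the 9 motifs. All 2080 6-mers, with reverse complements merged, were screened in the same way. A gene was bound if a reproducible summit lay between 1 kb upstream and the end of the gene. The 28 gene lists, whose symbols were updated for 8 members, were each compared with 10000 random lists matched on gene-length decile, by a two-sided permutation test adjusted over the 28 lists, and every p given for a list is the adjusted one. Promoter binding was tested likewise, matched also on the number of TSSs. The smallest p these permutations can give is 0.0002. Overlapping genes can share a summit, and ush stands on both the disc patterning and the hemocyte list. The name prefix that defined cuticle proteins also took in Cpr, which encodes a cytochrome P450 reductase.

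Genes named were the gene with the nearest coding TSS for the 20 strongest reproducible peaks found in the top lists of all 3 replicates, hry with every member of the HES and proneural lists, and up to 4 members of each other list with the strongest reproducible peak. The 10 named 6-mers had the largest ratio of summit to flank windows among those with adjusted p under 0.05 and at least 100 summit windows. Groups, tests, lists, naming rules and alternatives were fixed before the data were examined. The alternatives covered the overlap rule, list length, build, promoter distance, window size, control sequence, gene assignment, matching, the stronger part of the list (peaks above its median signal value), peaks in all 3 top lists, and each replicate left out in turn. Further alternatives, on the cuticle and ribosomal protein lists and on recovery by peak strength in the full replicate lists, were chosen after seeing the data. The annotated features of summits, their GC content, the split of the named 6-mers into promoter and distal peaks, and the number of summits around hry were also added after the data were seen.

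Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. The functions were tested on simulated data. A planted recovery of 79.6% was measured as 80.2% and a planted promoter share of 37.25% as 37.15%, over 10233 peaks, and 8 of 100 random peak sets passed 0.05 in the promoter test. A planted E-box share of 21.8% was measured as 21.7%, and 7 of 100 random peak sets had any motif called. The planted 6-mer ranked 1 in the screen. Over 20 simulated sets of 13945 genes, 1 list call was made without a planted effect, and a list of the size of the TCA cycle list, bound at 90%, was called in 14, so list tests of this size miss some effects.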

Results

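Binding of the Hairy-GFP fusion was measured by anti-GFP ChIP-seq in 3 biological replicates of whole wandering larvae. Hairy is a basic helix-loop-helix repressor of the HES family that represses genes together with corepressors such as Groucho. The labels state no question beyond where the fusion binds, so the lists were described for agreement between replicates, location, sequence and target genes. Values of single peaks are the authors' signal values, and read depth is unknown.

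The reproducible list held 10233 peaks with a median width of 430 bp, covering 2.56% of the 6 chromosome arms. The strongest peak, at 2L 480537 to 481436 with a signal value of 6471, lay in an intron of ush (FBgn0003963), 1364 bp from the TSS of cbt (FBgn0043364), which encodes a zinc-finger transcription factor. It ranked 1 in each replicate. The next strongest lay in an intron of CG11050 (2L 6612385 to 6612992, signal value 5819.6), and ranked 2 in each replicate. Peaks at CG14100 (3L 19590394 to 19590873) and Ugalt (X 2703669 to 2704120) followed, 91 and 44 bp from the nearest TSS, with mean replicate ranks of 3.33 ± 0.58 and 3.67 ± 0.58 (SD, n = 3).

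The other genes nearest to the 20 strongest peaks were CG1888, mRpL23, CG16753, Hsp27, Lk6, PNPase, ph-p, Tcs5, CG18549, SLC5A11, Chro, eEF1gamma, larp, CG13323, CG32772 and CG9147. The Hsp27 peak (3L 9383638 to 9384134, signal value 3916) lay 155 bp from the TSS of this small heat shock protein gene. The ph-p peak, at a Polycomb-group gene (X 2137029 to 2138279, signal value 3669.9), lay in an intron. Nearest genes were distant in some cases, with 5734 bp for CG16753, 5736 bp for eEF1gamma and 11979 bp for CG13323.

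At hry (FBgn0001168) itself, the strongest summit lay at 3L 8675721, 38 bp upstream of the TSS, in a peak from 8675087 to 8676130 with a signal value of 2191 and a rank of 58. Its mean replicate rank was 64.3 ± 36.9 (SD, n = 3). The gene, at 3L 8675759 to 8679253 on the plus strand, had 21 reproducible summits in the 40000 bp centred on its start, against a median of 4 over coding genes. The replicate top lists held 22 ± 1 summits there (SD, n = 3).

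**Figure D1:**
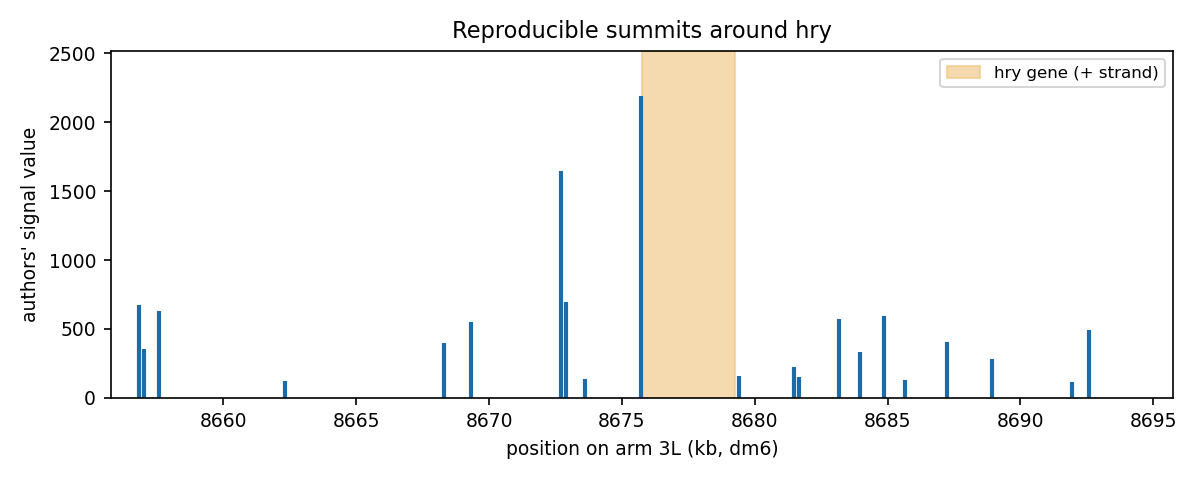
Reproducible summits in the 40000 bp centred on the start of hry, with position on arm 3L (kb, dm6) on the x axis and the authors' signal value on the y axis. Each bar is 1 of 21 summits and the shaded block is the gene; the tallest bar, 2191, stands 38 bp upstream of the TSS.

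Nearly all reproducible peaks were found in each replicate's full list of 30000 peaks, with a mean of 98.3% ± 0.80 (SD, n = 3). The shorter top lists of replicates 1, 2 and 3 held 89.2%, 88.7% and 84.0% of reproducible summits, with a mean of 87.3% ± 2.86 (SD, n = 3), against 2.72% for random placement. Each replicate lay above all 100 placements (permutation test, p = 0.0099, the smallest these can give). The reproducible list was made from these replicates, so recovery above random placement is not independent support. Summits in all 3 top lists numbered 7204, or 70.4%, and 53 were in none. With the list divided by signal value into 5 bins of equal size, recovery was 98.8% ± 0.59 in the strongest bin and 58.9% ± 3.80 in the weakest (SD, n = 3), as the plot of recovery by bin shows. In the full lists the weakest bin was recovered at 97.2% ± 1.80 (SD, n = 3), so the lower value in the top lists comes with their length.

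Pairs of top lists overlapped by 82.3% for replicates 1 and 2, 79.3% for 1 and 3, and 78.5% for 2 and 3, against a mean of 2.77% for random placement. Spearman's rho of signal values was taken across reproducible summits inside a peak of both full replicate lists, which numbered 9994, 9871 and 9844 for these pairs. It was 0.83, 0.77 and 0.76, a correlation across peaks, which are not independent replicates. At most 1.30% of summit positions were identical between a pair of replicates, so the replicate lists were not copies of one another.

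**Figure D2:**
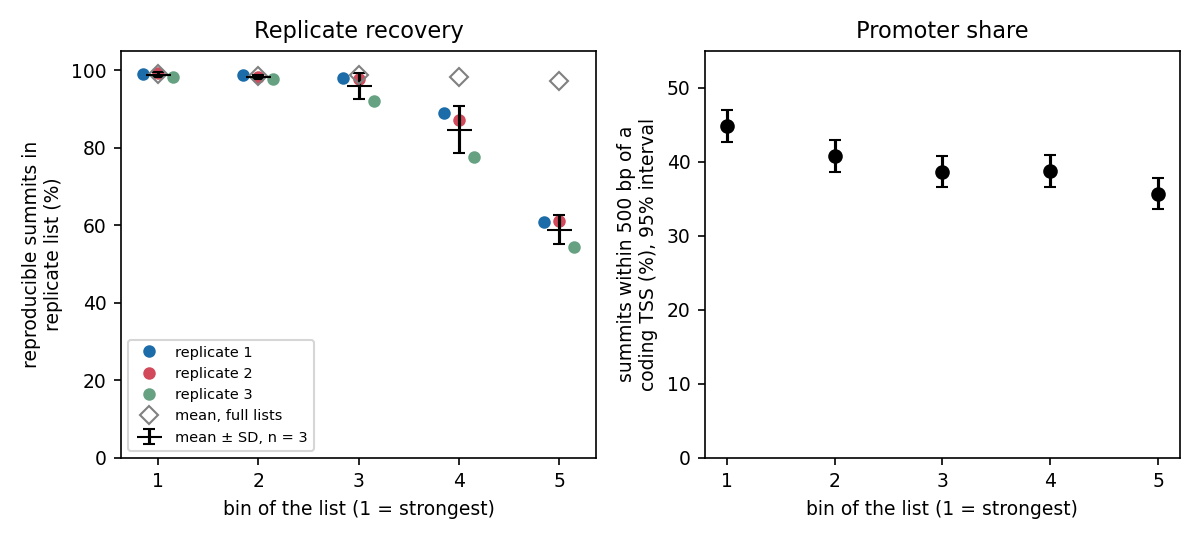
Percentage of reproducible summits found in each replicate's top list (left, points are replicates, bars mean ± SD, n = 3, diamonds the mean in the full lists) and within 500 bp of a coding TSS (right, exact 95% binomial interval), by bin of the list from strongest (1) to weakest (5). Recovery is 98.8% and 58.9% in the end bins of the top lists but 98.9% and 97.2% in the full lists, and promoter share falls from 44.8% to 35.7%.

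Binding was concentrated at promoters and rare in coding exons. Of the reproducible summits, 4067, or 39.7%, lay within 500 bp of a coding TSS, against 11.6% of random positions (two-sided Fisher's exact test, odds ratio 5.02, p too small to be represented). In pooled peaks outside the reproducible list the share was 21.0% (Fisher's exact test, odds ratio 2.48, p = 5.55e-254). The replicate top lists gave 40.4% ± 0.79 (SD, n = 3). The strongest bin had 44.8% at promoters (exact 95% interval 42.7 to 47.0) and the weakest 35.7% (33.6 to 37.8), with an adjusted p of 2.46e-08 by Fisher's exact test.

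By the annotation of protein-coding genes, 50.5% of summits lay in introns against 42.0% of random positions. Outside these genes lay 36.4% against 32.8%, and in 5' UTRs 10.9% against 3.42%. Coding exons held 0.69% against 16.8%, an odds ratio of 0.035, and 3' UTRs 1.47% against 4.88%. The replicate top lists gave 0.71% ± 0.11 for coding exons (SD, n = 3). The median distance to the nearest coding TSS was 1064 bp, and 24.2% of summits were farther than 5000 bp.

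The X chromosome was bound at about the density of the large autosome arms, and chromosome 4 at a lower one. Summits per Mb were 79.4 on 2L, 74.5 on 2R, 79.2 on 3L, 74.3 on 3R and 78.5 on X, and 18.5 on chromosome 4, which held 25 summits. The replicate top lists gave 77.0 ± 3.07 on X, 77.0 ± 0.68 on the pooled autosome arms and 18.3 ± 2.38 on chromosome 4 (SD, n = 3). The X to autosome ratio of 1.00 ± 0.049 (SD, n = 3) differed from 1 by less than the spread between replicates. In the stronger part of the list the chromosome 4 ratio was 0.153, against 0.242 in the whole list.

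Of the sites named for HES repressors, the class C site was more frequent at summits than in flanks, the N-box was less frequent, and the class B E-box was not called. Calls were common in either direction. Among all 2080 6-mers, 529 were called more frequent at summits and 900 in flanks, so a call alone does not set a site apart. Mean GC content was 38.4% at summits and 42.4% in flanks, and 8.82% of flank windows were centred inside a reproducible peak. The class B E-box CACGTG was within 100 bp of 2.11% of summits and in 2.53% of flanks, a ratio of 0.834 (exact McNemar test, adjusted exact p = 0.0628). The N-box CACNAG was less frequent at summits, at 20.3% against 23.0% (adjusted exact p = 7.73e-06). The class C site CACGCG, which Hairy prefers in vitro, was more frequent, at 6.24% against 4.42%, a ratio of 1.41 (adjusted exact p = 1.47e-08). In the replicate top lists these ratios were 0.90 ± 0.015, 0.91 ± 0.033 and 1.38 ± 0.049 (SD, n = 3). Against dinucleotide-shuffled summit sequence the class C ratio was 1.03 and was no longer called (adjusted exact p = 0.623), and the class B ratio of 0.667 was called lower (adjusted exact p = 3.75e-06). The class B E-box was also called lower with windows of 50 bp (0.688), a flank 500 bp away (0.809) and distal peaks (0.753). The N-box was not called with windows of 200 bp (ratio 0.966, adjusted exact p = 0.0615).

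The DRE TATCGATA, bound by DREF and BEAF-32, had the highest ratio of the 9 motifs, at 3.00% of summits against 0.55% of flanks (ratio 5.48, adjusted exact p = 4.23e-42). Ohler 1 (GGTCACAC), a core promoter element bound by M1BP, followed with 2.12% against 0.54% (ratio 3.95, adjusted exact p = 1.81e-23), and GAGA repeats with 12.6% against 8.51% (ratio 1.48, adjusted exact p = 4.80e-21). At distal peaks the DRE ratio was 0.595 (adjusted exact p = 0.0747) and the Ohler 1 ratio 0.966 (adjusted exact p = 1), so both calls rested on promoter peaks, where the ratios were 15.7 and 6.75. These promoter ratios compare summits with their flanks, and no unbound promoters were examined. They therefore cannot tell whether the DRE and Ohler 1 mark the promoters bound by the fusion or promoters in general. Ohler 1 was rarer in the strongest bin of peaks than in the weakest, at 0.83% against 2.39% (Fisher's exact test, adjusted exact p = 0.000294). No other motif differed between these bins after adjustment.

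Of the other motifs, the class A E-box CAGCTG was at 9.47% of summits and 8.94% of flanks (adjusted exact p = 0.223), CAGGTA at 4.29% and 4.48% (adjusted exact p = 0.539), and the CA repeat at 5.54% and 4.89% (adjusted exact p = 0.0545). None of these was called over all peaks. The class A E-box was called higher at promoter peaks, at 13.3% against 10.4% (ratio 1.28, adjusted exact p = 6.98e-05), and lower at distal peaks (ratio 0.836, adjusted exact p = 0.0113). Over all peaks it was called higher with windows of 200 bp (1.16) and against shuffled sequence (2.58). CAGGTA was called lower against shuffled sequence (0.801). The CA repeat was called higher at promoter peaks, at 5.78% against 3.81% (ratio 1.52, adjusted exact p = 6.44e-05), and not at distal peaks (ratio 0.962, adjusted exact p = 0.715). Over all peaks it was called lower with windows of 50 bp (ratio 0.802) or with a flank 500 bp away (0.831), and higher with windows of 200 bp (1.31) and against shuffled sequence (5.40).

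**Figure D3:**
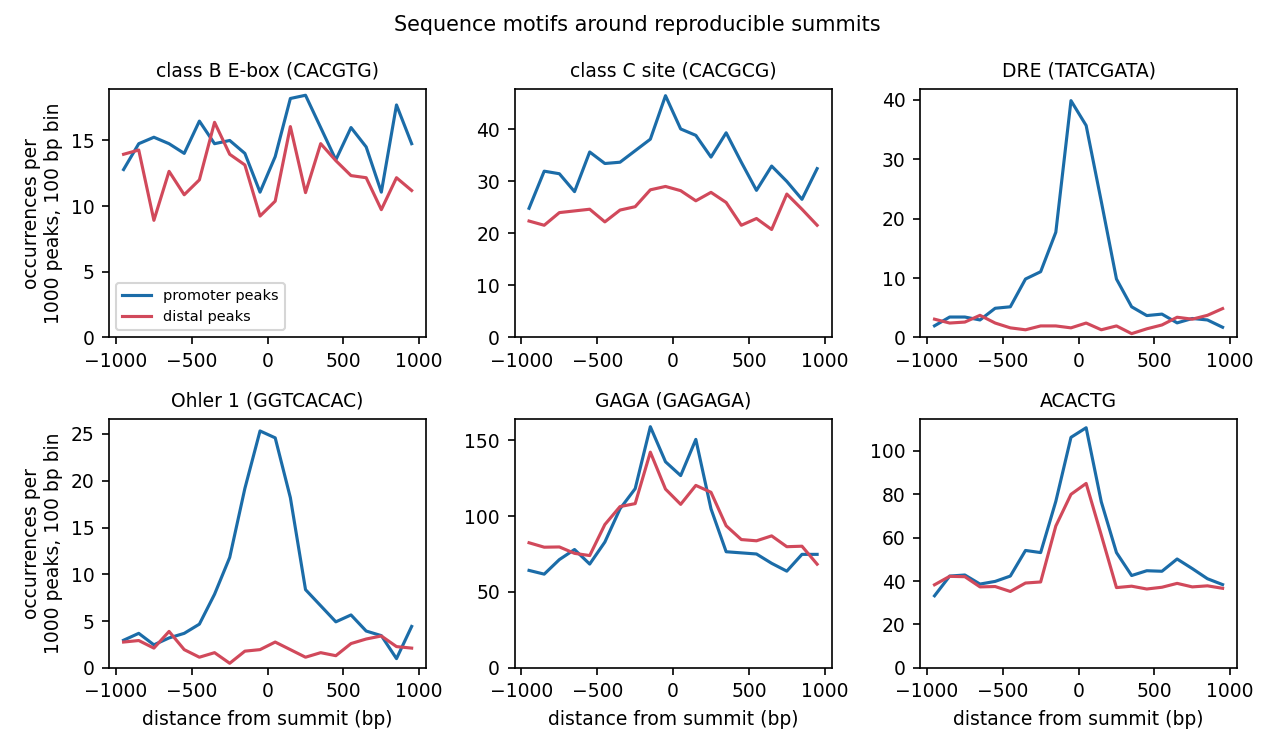
Occurrences per 1000 peaks in bins of 100 bp around the summits of promoter and distal reproducible peaks, for 5 fixed motifs and the 6-mer ACACTG, with distance from the summit (bp) on the x axis. DRE and Ohler 1 peak at the summits of promoter peaks alone, ACACTG at the summits of both kinds, and the class B E-box at neither.

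In the screen of 2080 6-mers, 529 were more frequent at summits and 900 in flanks, with a mean GC content of 38.4% at summits and 42.4% in flanks. The largest ratios were those of ACACTG (16.6% of summits, 7.62% of flanks, ratio 2.18, adjusted exact p = 2.73e-84), CGATAG (1.99), ACAGTG (1.98), AGTGTA (1.92) and GTGCAC (1.83). CACTGA (1.80), CAGTGC (1.68), CTACAC (1.68), ATACTA (1.66) and TATCGA (1.66) followed. CGATAG and TATCGA share bases with the DRE, and unbound promoters were likewise not examined for them. They had ratios of 3.79 and 2.79 at promoter peaks and 0.91 and 1.00 at distal peaks. GTGCAC went the other way, with 1.04 at promoter peaks (adjusted exact p = 0.757) and 2.25 at distal peaks (adjusted exact p = 1.62e-30). The remaining 7 named 6-mers were called higher in both sets, among them ACACTG (2.54 at promoter and 1.97 at distal peaks), ACAGTG (1.74 and 2.28) and CTACAC (1.21 and 1.87). The named 6-mers were chosen by their ratio over these same peaks, so calls within promoter and distal peaks are not independent support. ACACTG, ACAGTG, CACTGA and CAGTGC all contain CACTG or its reverse complement, so they are not separate results. AGTGTA reads TACACT on the other strand, which shares ACACT with ACACTG and TACAC with CTACAC. ACACTG also starts with ACAC, the end of Ohler 1, so the promoter ratios of these 2 may not be independent.

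Genes of Hairy's own family were not called above matched genes in the reproducible list. Of 13 HES family genes, 8 were bound, or 61.5%, against 29.2% of length-matched genes (permutation test, adjusted permutation p = 0.0543), and each replicate top list gave the same 61.5%. After hry, the strongest by pooled signal value were E(spl)m7-HLH (signal value 740.4), dpn (738.6), cwo (515.4), E(spl)m3-HLH (487.1), E(spl)mbeta-HLH (486.5), E(spl)mdelta-HLH (434.4) and Sidpn (164.6). The E(spl)m7-HLH peak ranked 859, 707 and 7156 in the 3 replicates, and that of dpn 861, 626 and 871, so the place of E(spl)m7-HLH differed between replicates. No summit was assigned to E(spl)mgamma-HLH, E(spl)m5-HLH, E(spl)m8-HLH, Hey or Hesr. This list passed the threshold under 4 of its alternatives, with adjusted permutation p from 0.0149 to 0.0476. Of 10 proneural and other bHLH genes, da and emc were bound, and ac, sc, l(1)sc, ase, ato, amos, cato and tap were not (matched genes 29.0%, adjusted permutation p = 0.831).

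Of 28 lists, 5 were bound above and 3 below length-matched genes, and 5120 of 13945 coding genes, or 36.7%, were bound. Cytoplasmic ribosomal proteins stood highest above their matched genes, with 76 of 92 bound, or 82.6% against 25.6% (permutation test, adjusted permutation p = 0.0014), and 81.5% ± 2.88 in the replicates (SD, n = 3). Their strongest peaks lay at RpL7 (2L 10200856 to 10201187), RpL34b, RpL32 and RpS27, all within 148 bp of a TSS. Within 100 bp of its summit, the RpL7 peak held both a class B and a class C site. The peaks of RpL34b, RpL32 and RpS27 held neither. In other lists, a peak assigned to a gene by its span could lie at another gene's promoter. Within 500 bp of a TSS, the nearest TSS belonged to another gene for the strongest peaks of E(spl)mdelta-HLH, stg, dup (25 bp from SRPK), Fum1, ND-39, ND-MWFE, ND-15 (49 bp from CG3164), Cpr51A, Mlc2, Tm1 and topi, and for 3 chemosensory receptor genes given with their list.

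Ecdysone response genes, which act downstream of the moulting hormone, were bound at 20 of 21, or 95.2% against 57.3% (permutation test, adjusted permutation p = 0.0014), and 93.7% ± 2.75 in the replicates (SD, n = 3). Eip75B, a nuclear receptor gene, held 35 reproducible summits, the strongest in an intron at 3L 18011925 (signal value 2607), and Eip78C, Hr4 and Eip63E followed. All 12 EGFR pathway genes were bound against 60.5% (adjusted permutation p = 0.0131), led by aop, edl, Krn and spi, with 94.4% ± 9.62 in the replicates (SD, n = 3). Of the Hippo pathway and growth genes 13 of 14 were bound against 54.8% (adjusted permutation p = 0.0168), led by Diap1, ds, ex and Myc, with 95.2% ± 4.12 in the replicates (SD, n = 3). With a window from 5 kb upstream to 1 kb past the gene, neither list was called (adjusted permutation p = 0.113 and 0.130), although the shares bound stayed at 100% and 92.9%. With peaks in all 3 top lists, 83.3% of the EGFR list was bound and it was not called (adjusted permutation p = 0.147).

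TCA cycle genes were bound at 15 of 18, or 83.3% against 41.9% (permutation test, adjusted permutation p = 0.00448), led by Fum1, Idh3g, mAcon1 and Idh, with 75.9% ± 3.21 in the replicates (SD, n = 3). The call ended when summits went to the nearest TSS alone, with 66.7% bound (adjusted permutation p = 0.0548), and in the stronger part of the list, with 55.6% bound (adjusted permutation p = 0.0734). Other metabolic lists were not called. Of 13 glycolysis genes 8 were bound against 41.9% (adjusted permutation p = 0.346), with Gapdh2 (signal value 2976), Eno, Hex-A and Ldh leading, and of 80 oxidative phosphorylation genes 27, or 33.8% against 25.1% (adjusted permutation p = 0.212), with ND-ASHI, ND-39, ND-MWFE and ND-15. The Fum1 and ND-ASHI peak is the same one. The oxidative phosphorylation list also took in members whose symbols add an L to that of a subunit. Among these, COX4L, ND-20L and UQCR-11L were not bound and COX7AL2 was. The list was not tested without such members, which may lower its share.

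Chemosensory receptor and cuticle protein genes were bound less often than their matched genes. Chromatin came from whole larvae, so binding in a small share of cells could go uncalled in these and the tissue lists. Of 179 chemosensory receptor genes 6 were bound, or 3.35% against 31.3%, and of 118 cuticle protein genes 8, or 6.78% against 24.3% (permutation test, adjusted permutation p = 0.0014 for both), with 3.72% ± 0.65 and 6.21% ± 0.49 in the replicates (SD, n = 3). The receptor genes with the strongest peaks were Ir94h, Or9a, Ir60e and Gr97a, of which the last 3 peaks lay nearest to the TSS of another gene, 69 bp from Neb-cGP, 26 bp from CG13585 and 226 bp from CG5521. The cuticle genes were Cpr72Eb, Cpr62Ba and Cpr51A, besides Cpr, the cytochrome P450 reductase gene. Of 12 neuronal differentiation genes 3 were bound, elav, ChAT and futsch, or 25% against 65.8% (adjusted permutation p = 0.0266). That call ended with the nearest TSS alone, the window from 5 kb upstream, the stronger part of the list and unmatched lists (adjusted permutation p from 0.128 to 0.840), and 41.7%, 58.3%, 16.7% and 25% were bound there.

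**Figure D4:**
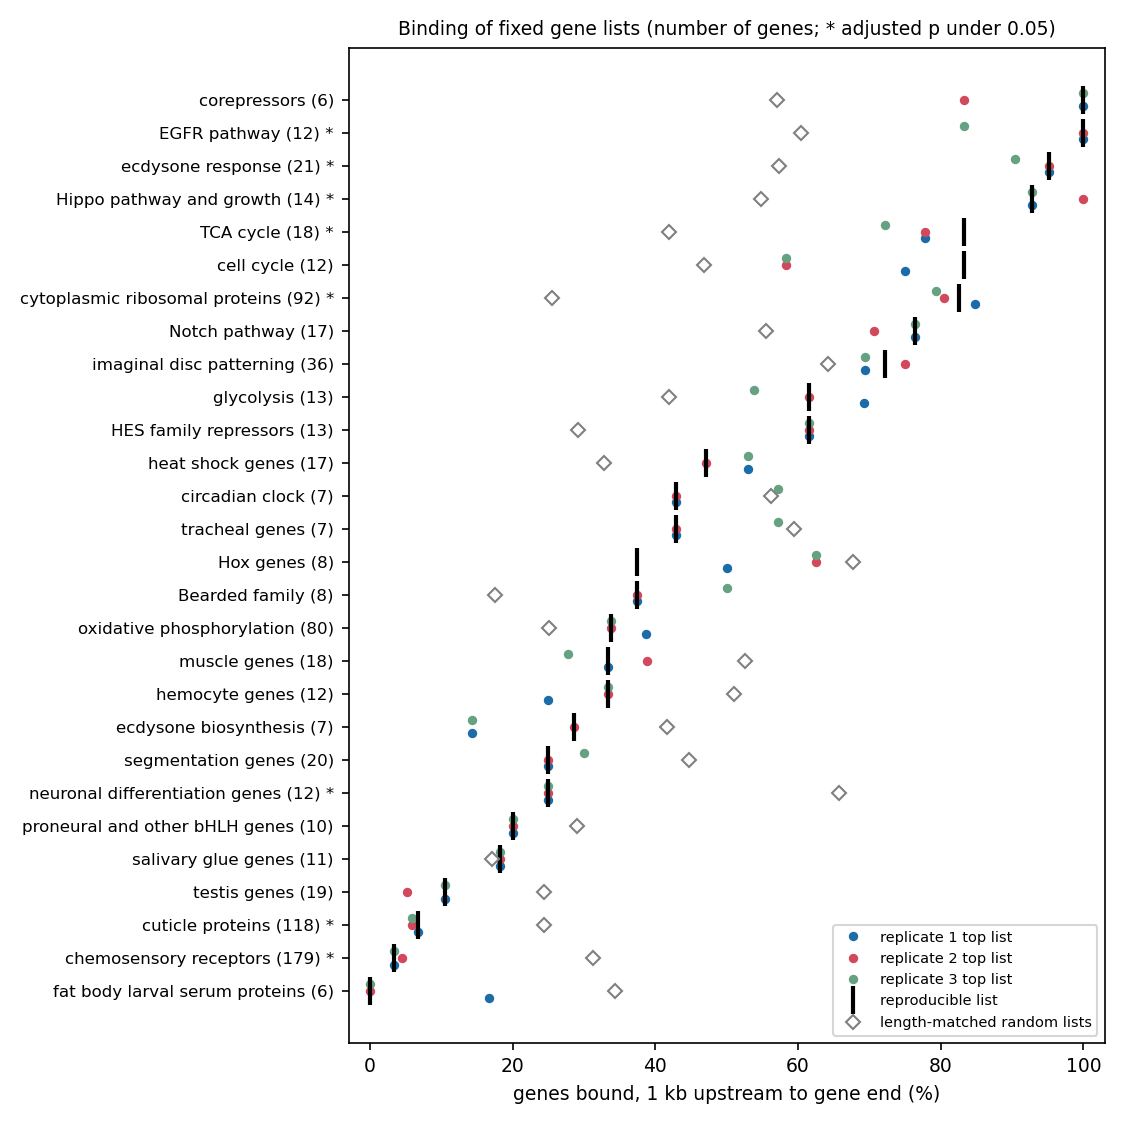
Percentage of genes bound from 1 kb upstream to the gene end (x axis) for the 28 fixed lists, with the number of genes in parentheses. Bars mark the reproducible list, points the 3 replicate top lists, and diamonds the mean of length-matched random lists; asterisks mark the 8 lists with adjusted p under 0.05.

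The other developmental lists were not called. All 6 corepressor genes were bound against 57.0% (permutation test, adjusted permutation p = 0.138), with gro, the gene for Groucho, strongest (3R 26042316 to 26042690, signal value 1299), then Sin3A, Smr and CtBP. Of 17 Notch pathway genes 13 were bound against 55.6% (adjusted permutation p = 0.227), led by mam, neur, fng and N, and of 8 Bearded family genes 3 against 17.6% (adjusted permutation p = 0.401), E(spl)m2-BFM, Brd and Tom. Cell cycle genes were bound at 10 of 12 against 46.9% (adjusted permutation p = 0.0543), with stg, E2f1, dup and Cdk4 leading, and 63.9% ± 9.62 in the replicates (SD, n = 3). Imaginal disc patterning genes were bound at 26 of 36 against 64.2% (adjusted permutation p = 0.471), with ush, Dad, dpp and bab1.

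Segmentation genes were bound at 5 of 20 against 44.7% (permutation test, adjusted permutation p = 0.212), led by knrl, cad, bcd and hh, and Hox genes at 3 of 8 against 67.7% (adjusted permutation p = 0.260), namely Antp, Ubx and lab. The replicate top lists bound 58.3% ± 7.22 of the Hox genes (SD, n = 3). For ecdysone biosynthesis the count was 2 of 7, shd and sro, against 41.7% (adjusted permutation p = 0.816). Circadian clock genes had 3 of 7, vri, cry and Pdp1, against 56.2% (adjusted permutation p = 0.813). Tracheal genes had 3 of 7, trh, bnl and stumps, against 59.5% (adjusted permutation p = 0.692). The strongest trh summit lay inside a peak of the full list of replicate 2 alone. That of Ubx lay inside peaks of the full lists of replicates 1 and 3, but not of replicate 2.

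Among the lists that stand for tissues, muscle genes were bound at 6 of 18 against 52.5% (permutation test, adjusted permutation p = 0.260), with Mef2, Zasp52, Mlc2 and Tm1, and hemocyte genes at 4 of 12 against 51.0% (adjusted permutation p = 0.401), with ush, srp, lz and Ppn. Salivary glue genes had 2 of 11, Sgs5 and Sgs1, against 17.1% (adjusted permutation p = 1), larval serum proteins of the fat body 0 of 6 against 34.3% (adjusted permutation p = 0.260), and testis genes 2 of 19, can and topi, against 24.3% (adjusted permutation p = 0.346). Heat shock genes had 8 of 17 against 32.8% (adjusted permutation p = 0.401), with Hsp27, Hsp83, Hsp26 and Hsp22.

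At promoters alone, 2 lists were above and 4 below matched genes. Ribosomal protein promoters were bound at 73 of 92, or 79.3% against 31.8% (permutation test, adjusted permutation p = 0.00187), and TCA cycle promoters at 13 of 18, or 72.2% against 40.1% (adjusted permutation p = 0.0381). The promoters of chemosensory receptor genes (2 of 179) and cuticle protein genes (3 of 118) were below (adjusted permutation p = 0.00187 for both), as were those of neuronal differentiation genes (2 of 12, adjusted permutation p = 0.0401) and Hox genes (0 of 8 against 48.9%, adjusted permutation p = 0.0381). The Hox, neuronal and TCA calls were lost in the stronger part of the list, with adjusted permutation p of 0.338, 0.304 and 0.651, where 0 of 8 Hox, 8.33% of neuronal and 38.9% of TCA cycle promoters were bound. The Hox call was also lost within 200 bp of a TSS (adjusted permutation p = 0.144), where the share was again 0 of 8, as it must be with fewer summits counted. Ecdysone response, EGFR and Hippo promoters, bound at 15 of 21, 8 of 12 and 7 of 14, were not called (adjusted permutation p = 0.274, 0.295 and 0.568). Within 1000 bp of a TSS the EGFR and Hippo promoters were called above matched genes (adjusted permutation p = 0.0112 for both), and those of muscle genes below (0.0175).

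The dm3 lists gave close counts, with 10304 reproducible peaks against 10233 on dm6. The arm totals on dm6 and dm3 were 1847 and 1895 for X, and 25 and 21 for chromosome 4.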

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

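No outlier test was made, since a group of 3 replicates is too small for the test used, and there was no other group to compare. Replicate 3 was the lowest in agreement, with a recovery of 84.0% against 89.2% and 88.7%, and a Spearman's rho across peaks of 0.77 and 0.76 with the other replicates, against 0.83 between replicates 1 and 2. Without replicate 3 the pairwise overlap was 82.3%.

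Peaks on dm3 sequences outside the 6 main arms entered only the totals and alternatives taken over whole dm3 lists, and were not examined further. These sequences held 32 peaks in the pooled list, and 39, 25 and 31 in the lists of replicates 1, 2 and 3, each of 30000 peaks. The counts are above 3, the limit that a count of 0 allows, but no background level was measured for these sequences, so whether they hold more peaks than background was not tested. Only 2 of these peaks were in the dm3 reproducible list, and the dm6 lists hold 0 peaks outside the arms.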

How the results depend on the processing

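No paired analysis was possible because there is 1 group. Alternatives were planned, except the cuticle list without Cpr (5.98% bound) and the ribosomal protein list without members ending in -like (85.1%), and recovery by bin in the full lists, chosen after seeing the data. Both list calls held, and recovery in the weakest of 5 bins by signal value was 97.2% in the full lists against 58.9% in the top lists. Read depth is unknown and limits what weak peaks can show. The cause was not tested for the changes given here, unless the alternative itself takes in fewer peaks.

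Recovery was 83.8% with summits within 100 bp, 98.3% in the full lists and 98.3% for the stronger part of the list. Pairwise overlap was 74.3% with summits within 100 bp, 85.7% for the top 1000, 70.6% for the full lists, and 78.5% to 82.3% with a replicate left out. The X to autosome ratio was 0.949 in the stronger part and 0.960 per gene span, and that of chromosome 4 was 0.153 in the stronger part. Promoter share stayed above random under each alternative, from 29.3% within 200 bp to 49.1% within 1000 bp.

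The class B E-box became called lower with a 50 bp window (ratio 0.688), the shuffle (0.667), a flank 500 bp away (0.809) and distal peaks (0.753), and the class C call was lost with the shuffle (1.03). At distal peaks ratios turned for the class A E-box (0.836), DRE (0.595), CAGGTA (1.16), Ohler 1 (0.966) and the CA repeat (0.962). With a flank 500 bp away they turned for the class A E-box (0.988) and the CA repeat (0.831), the latter also in a 50 bp window (0.802). Distal peaks left 2 motifs called higher, against 4. Motifs called lower, 1 in all peaks, were 3 with 50 bp windows, 0 with 200 bp, and 3 each with the shuffle, the near flank and distal peaks.

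Unmatched random lists called 9 gene lists higher, against 5. For promoters the lists called higher were 4 within 1000 bp and 1 in the stronger part, against 2, and those called lower were 2 in the stronger part, against 4. No list called in the reproducible peaks turned its direction, and over their alternatives, the added ones included, calls were kept 33 times and lost 9 times for binding, and kept 14 times and lost 4 times for promoters. Lists not called gained a call 10 and 3 times. Directions turned for uncalled lists alone. With the nearest TSS these were proneural (60%), segmentation (50%), Hox (75%), clock (57.1%) and tracheal genes (57.1%). In the stronger part they were proneural (20%), disc patterning (44.4%) and clock genes (42.9%). With unmatched lists they were Hox (37.5%), clock (42.9%), tracheal (42.9%), oxidative phosphorylation (33.8%) and glue genes (18.2%), and with the window from 5 kb upstream glue genes (27.3%). For promoters they were proneural (20%) and Bearded genes (12.5%) within 200 bp, Bearded genes (37.5%) within 1000 bp, and in the stronger part proneural (20%), Notch (23.5%), disc patterning (22.2%) and cell cycle genes (16.7%).

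By mean replicate rank the strongest minus the weakest bin turned for the class B E-box (0.35 percentage points) and the DRE (-1.39), neither called. With a replicate left out, mean recovery was 86.3% to 88.9%, mean promoter share 40.0% to 40.7% and the mean X to autosome ratio 0.972 to 1.02. A mean of 3 values moves little by construction when 1 is left out, so these ranges do not test stability.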

Other observations

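Of the tests here, only that of ribosomal protein genes away from other promoters was set down before its result was seen. Those of weak peaks, distal peaks and shuffled sequence for HES-type sites, and that of extra copies around hry, were chosen after results they rest on had been seen.

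Among the 92 ribosomal protein genes, the 16 without a summit included 3 of the 5 whose symbols end in -like, RpL22-like, RpL24-like and RpS28-like, and also RpL5, RpL15, RpS3 and RpS26. These were named after their values were seen.

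Around hry, 21 reproducible summits lay in 40000 bp, and 10 of 13945 coding genes, hry included, had as many or more in a window of that size, among them aop and tara with 23 each. One hypothesis is that extra copies of the hry region in the transgenic line raise the number of called peaks, which would also raise weaker peaks there. The window held 21 weaker pooled peaks, above the median of 13.5 but below the highest of 31 over 24 genes elsewhere with at least 18 reproducible summits, a number chosen with the densest windows known. Windows of neighbouring genes can overlap and count the same summits, so these genes may stand for fewer separate regions. Extra copies and denser binding cannot be told apart, because the extent of the construct is unknown and control data were not analysed here. No biological explanation was tested.

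Of the HES-type sites, the N-box and the class B E-box were not above flanks at summits, while the class C site was. Weak peaks may dilute sites that strong peaks hold. Among peaks above the median signal value the N-box ratio was 0.883 to flanks and 0.880 to shuffled sequence (exact McNemar test, adjusted p = 0.00254 and 0.00111). Weaker peaks therefore hid no excess of that site in this part of the list as a whole. Sites held by a small share of strong peaks would not be seen, so dilution is not excluded. Over all reproducible peaks, GC content was also lower at summits (38.4%) than in flanks (42.4%). For the class B E-box these ratios were 0.870 and 0.686 (exact McNemar test, adjusted p = 0.464 and 0.00345), so dilution by weak peaks stays open. At distal peaks the class B ratios were 0.753 and 0.678 (exact McNemar test, adjusted p = 0.0407 and 0.00178), so promoter peaks hid no excess in distal peaks as a whole. The class C site was not called above dinucleotide-shuffled summit sequence, with a ratio of 1.03. The choice of control matters, since the class A E-box had ratios of 1.06 to flanks and 2.58 to shuffled sequence. Flanks were not compared with their own shuffles, so whether composition accounts for the class C excess over flanks cannot be decided. Recruitment through other proteins was not tested, and no biological explanation was tested because the design gives 1 group.

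The binding of ribosomal protein genes may reflect summits of neighbouring promoters counted for short genes. Among 7960 coding genes with no other coding gene's TSS within 1000 bp, 25 of 34 ribosomal protein genes were bound, or 73.5%, against 15.0% of length-matched genes in that set (permutation test, p = 0.0002, the smallest these can give), which argues against neighbours as the cause. Whether binding at these genes follows their transcription stays open, because expression was not analysed here, and no biological explanation was tested. Without control data, signal that does not depend on the fusion cannot be told from its binding at these genes.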
